A study of Mus musculus with 4 samples.

How the data were processed

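Rad21 chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed in 4 libraries from mouse v-Abl transformed pro-B cell lines, 2 wild type (WT) and 2 with a 53BP1 knockout. Per the labels' protocols, RAG-deficient cells carrying an Emu-Bcl2 transgene were treated with 3 uM STI-571 for 4 days, fixed with 1% formaldehyde, sonicated and immunoprecipitated, and libraries were made by tagmentation on the beads. Groups and replicate numbers were taken from the sample titles. Peak lists hold no measure of 53BP1 itself, so the genotypes rest on the labels. The labels disagree on the antibody. Titles and the extraction protocol name Rad21, a subunit of cohesin, while the treatment field of every sample names a 53BP1 antibody. The libraries are called Rad21 libraries here after the titles and the protocol.

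The submitters' processing notes name Bowtie2 2.4.4, SAMtools 1.15.1, deepTools 3.5.1, MACS2 2.2.7.1 and the mouse build mm9. Their parameters, and whether an input library served as control, are not given in the sources used here. Each library had its own peak list of 9 columns without a header, in the layout of a MACS2 broad peak file, so peaks were called per library and not on pooled samples. The deposited fold enrichment is a ratio of each peak's signal to its background, as the authors' caller gave it. The deposited significance columns are −log10 p and −log10 q per peak, and the lowest −log10 q in the lists was 1.01 to 1.02. The deposited score is 10 times the −log10 q, truncated to a whole number, and was checked to differ from it by at most 1. Fold, p and q belong to one list and were used mainly to describe, rank or filter peaks inside that list. Across lists, regions that followed genotype were ranked by the lower of their folds. The same thresholds of fold or q were also applied to every list, so counts under them depend on the scale of each list. The lists give no read counts, so the sequencing depth of each library is unknown, and a library with fewer reads or weaker enrichment lists fewer or weaker peaks for that reason alone.

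The lists fit mm9 and not GRCm38: peaks on chromosome 1 ended as far as position 197182419, while the last gene of the GRCm38 table ends at 195291439. No genome or annotation of mm9 was used here, so peaks carry coordinates but no gene names, and the planned shares of genomic features, the 7 planned gene lists and the planned CTCF motif search were not run. Antigen receptor loci were taken as approximate mm9 windows set from background knowledge before the data were examined. Coordinates are 1-based.

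Peaks on chromosomes 1 to 19 and X were used. No list had a peak on Y or on an unplaced sequence, and peaks on the mitochondrial sequence were set aside. Peaks of all 4 lists that touched or overlapped were merged into regions, and a region counted as present in a library if one of its peaks lay in the region (overlap of at least 1 bp). Libraries were compared by the base-pair Jaccard index (shared over combined length) and by the percentage of peaks that overlapped a peak of the other list, averaged over both directions. Group means were compared with a two-sided exact permutation test over the 6 arrangements of 2 against 2 libraries, which cannot give a p below 0.333. This permutation test can therefore not pass 0.05 between the genotypes, and no p was computed per region. Fisher's exact test, two-sided, compared regions inside and outside the receptor loci, with Benjamini-Hochberg adjustment over 6 loci. It treats regions as independent and describes these 4 libraries, not the genotypes. Nothing in the labels says whether the 2 libraries of a genotype came from separate cultures or clones, so spread between them may be technical. No list was a copy of another, since no pair shared more than 80.2% of peaks. This overlap does not show that the duplicates were separately made libraries.

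The peak names carry a prefix that was the same for both libraries of replicate number 1 and for both of number 2. It was treated as a possible batch, and differences within each prefix are given. Differences of 1 Mb window counts between the 2 replicate numbers, with counts scaled to each library's total, had a correlation of 0.03 across windows between WT and knockout. The numbers were therefore not treated as pairing the libraries. The median window held 8.25 peaks, and such counts vary by counting error, so this low correlation cannot exclude a batch.

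Regions named in the text followed a rule set before the data were examined: up to 10 regions per direction that followed genotype, ranked by the lower of their 2 folds; the 5 strongest regions of all 4 libraries by within-list percentile of fold; in each receptor locus the strongest shared region and up to 5 that followed genotype; up to 5 windows of 1 Mb per direction, by the gap between the genotypes; and up to 5 chromosomes whose shares did not overlap between genotypes. Where a rule gave many items, the first ones are printed. Ties between windows, which the rule did not cover, were taken in chromosome order. Alternatives were a −log10 q of at least 5, a fold of at least 4, the same number of peaks from every list (the top 21971 by −log10 p), all sequences, autosomes only, merging within 1 kb, a reciprocal overlap of 50%, windows of 5 Mb, a replicate block and leaving out each library. Leaving out chromosomes 5 and 10 was added after the data were seen. Wilson intervals (95%) of shares of peaks cover counting error only. The merging and pattern counts were tested on simulated data: 20000 simulated regions with known patterns gave all 15 pattern counts exactly under both overlap rules. Simulated peaks of a region shared the same end and most of their length, so partial overlaps and chains of peaks were not tested. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.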

Results

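Genome-wide Rad21 binding was profiled in G1-arrested v-Abl transformed pro-B cells with and without 53BP1. Rad21 is the kleisin subunit of cohesin, the ring complex that forms chromatin loops, and 53BP1 is a chromatin-bound factor of DNA double-strand break repair. v-Abl lines are B cell progenitors immortalised by a viral kinase. STI-571, an inhibitor of that kinase, arrests them and starts recombination of the antigen receptor genes, and the Bcl2 transgene keeps arrested cells alive. These lines lacked RAG1, the nuclease subunit that starts V(D)J recombination. The data were 4 lists of broad peaks, 2 for WT and 2 for 53BP1 knockout cells, with positions in mm9. The WT lists held 21971 and 23029 peaks and the knockout lists 25145 and 22792 peaks on the placed chromosomes. Median folds of the lists, the authors' own values, were 4.10 and 4.06 for WT and 4.15 and 3.67 for the knockout. Read depth per library is unknown.

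The first comparison asked whether cohesin occupied more or fewer sites without 53BP1. Rad21 peaks numbered 22500 ± 748 in WT and 23969 ± 1664 in knockout cells (mean ± SD, n = 2 each), a difference of 1468.5 peaks or 1.07-fold. Peaks covered 12.7 ± 0.22 Mb in WT and 13.8 ± 0.72 Mb in knockout cells, 1.09-fold more. Median peak widths were 512 and 509 bp in WT, against 476 and 564 bp in the knockout libraries, which lay on either side of both WT values. At 14224 regions with exactly 1 peak in each library, median widths were 590 and 591 bp in WT and 565 and 651 bp in knockout cells. The second knockout list had fewer strong peaks: 16.5% of its peaks reached a −log10 q of 5 (Wilson interval 15.98 to 16.94%), against 27.0% and 27.7% in WT and 25.9% in the first knockout list, a share that moves with read depth. The exact permutation test gave p = 0.667 for peak number, 0.333 for covered length and 1 for width, with 0.333 the lowest p possible. Within the shared name prefixes, knockout minus WT was 3174 peaks, 0.787 Mb and −36 bp of width for replicate 1 and −237 peaks, 1.49 Mb and 55 bp for replicate 2. The difference was 292 peaks without the first knockout library and 0.629 Mb and −34.5 bp without the second, and among peaks with a −log10 q of at least 5 it was −1021 peaks and −0.68 Mb.

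The next comparison asked whether libraries of one genotype shared more sites than libraries of different genotypes. Most Rad21 sites were common to both genotypes. A mean of 75.8% ± 1.4 of peaks overlapped between a WT and a knockout library (SD, n = 4 pairs), and 76.6% between libraries of the same genotype (n = 2 pairs). The most similar pair was the 2 WT libraries, with 80.2% of peaks shared and a Jaccard index of 0.482. The least similar pair was the 2 knockout libraries, with 73.0% shared and an index of 0.420, below all 4 pairs of different genotype (0.428 to 0.464). The mean Jaccard index within genotypes exceeded that between genotypes by 0.008, less than the SD of 0.018 among the between-genotype pairs. The difference was 0.007 among peaks with a −log10 q of at least 5 and 0.006 with the same number of peaks from every list. Among peaks with a fold of at least 4 it was −0.003. Of the 3 ways to divide 4 libraries into pairs, the genotype pairing gave the highest mean index, 0.451, against 0.446 for pairs of the same replicate number and 0.441 for the crossed pairs. With 3 pairings no share below 0.05 can be reached. Leaving out either WT library made the difference of the indices negative, −0.021 and −0.026, while leaving out the first or the second knockout library gave 0.054 and 0.023.

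Regions were then sorted by the libraries that held them, to find sites that followed genotype. Of 34743 merged regions, 14484 (41.7%) were called in all 4 libraries and 10658 (30.7%) in a single one. Both knockout libraries and neither WT library called 1058 regions, and both WT libraries and neither knockout library called 760. Together these 1818 regions were 5.23% of the total. The 4 mixed pairs of one WT and one knockout library gave 1009, 849, 738 and 474 regions of their own, so 1058 lay above and 760 within the range that pairs mixing genotypes gave. The largest class missing from one library was absent from the second knockout list alone, with 1906 regions. Genotype-only regions were weak within their lists, with median fold percentiles of 28.8 to 37.3, against 27.1 to 36.9 for regions of mixed pairs, also called in 2 libraries, and 58.6 to 66.3 for regions of all 4 libraries. The 760 and 1058 depended on list length: with the same number of peaks from every list WT-only regions became the more numerous, 921 against 796, and at a −log10 q of at least 5 they were 470 against 169.

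**Figure D1:**
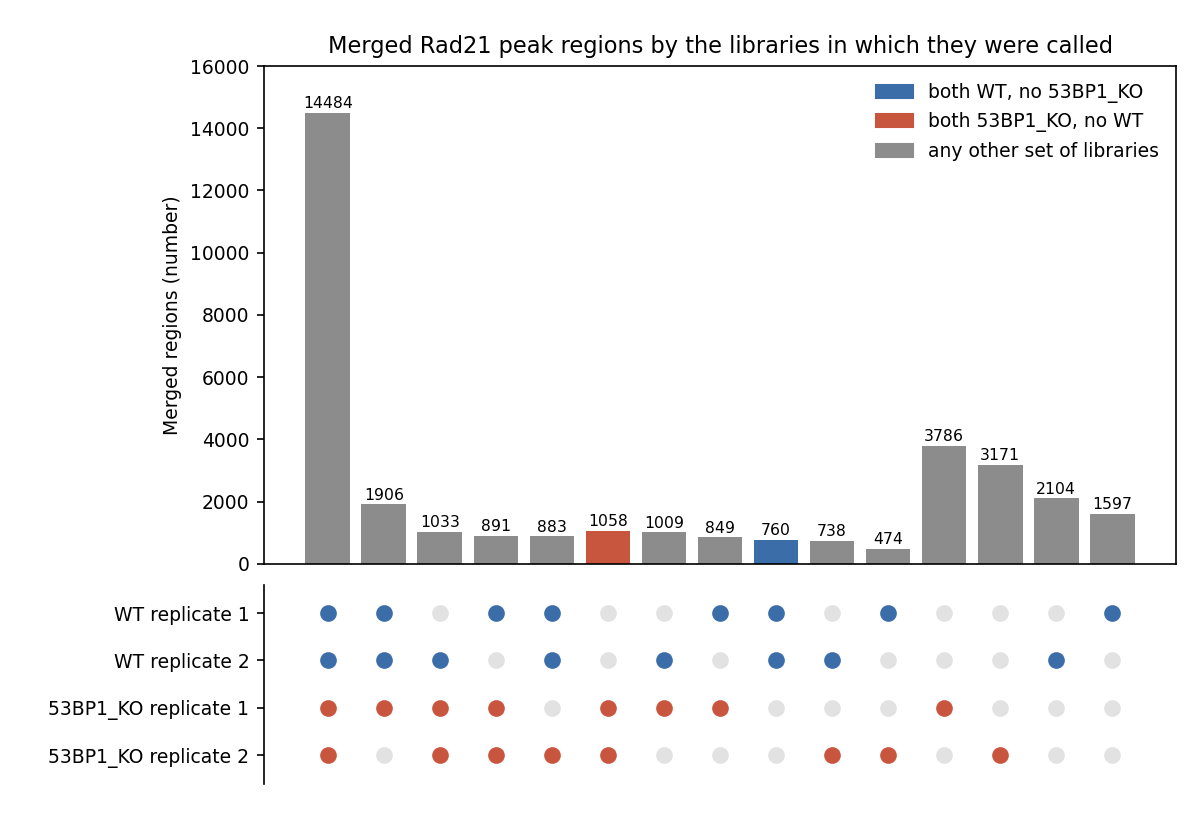
Number of merged Rad21 regions (vertical axis) for each of the 15 sets of libraries that called them, with filled dots marking the libraries of a set. The 14484 regions called in every library are the tallest bar, and the 1058 knockout-only and 760 WT-only regions stand beside mixed pairs of 474 to 1009.

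Ranked by the lower of the folds in both lists, the first knockout-only region lay on chromosome 12 at 121045829 to 121046677, with folds of 5.86 and 5.60 in knockout replicates 1 and 2. The next ones were chromosome 5 at 144046141 to 144046796 (folds 5.59 and 5.33), chromosome 11 at 31273350 to 31273897 (5.22 and 5.47) and chromosome 12 at 25049077 to 25049561 (6.18 and 5.15). By the same ranking, the first WT-only region lay on chromosome 4 at 3018382 to 3018716, with folds of 5.37 and 6.20 in WT replicates 1 and 2. It was followed by chromosome 6 at 30896932 to 30897260 (5.13 and 6.45), chromosome 1 at 177533278 to 177533982 (5.36 and 5.10) and chromosome 17 at 79606047 to 79606393 (5.95 and 5.08). In both knockout lists 3 of the 1058 regions reached a −log10 q of 5, and in both WT lists 0 of the 760 did. In contrast, 2330 of the regions called in all 4 libraries reached it in every list. The 5 strongest shared regions, ranked by their lowest within-list percentile of fold, had folds from 17.0 to 24.1. They lay on chromosome 6 at 103598979 to 103599361, chromosome 12 at 3109798 to 3110192, chromosome 9 at 35112762 to 35113239, and chromosome X at 166527145 to 166527582 and 166649928 to 166650296. No gene is assigned to these regions, since no mm9 annotation was used here. No repeat annotation was used either, so named regions on repeated sequence, if any, were not set aside.

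In the antigen receptor loci V(D)J recombination takes place, and cohesin-driven loop extrusion brings distant gene segments together. Of these loci Igh, Igk and the joint locus of Tcra and Tcrd were densely occupied in both genotypes. The Igh window (immunoglobulin heavy chain) held 108 peaks in each WT library and 108.5 ± 7.78 in knockout libraries (mean ± SD, n = 2). The Igk window (kappa light chain) held 101 and 97 in WT and 109 and 104 in knockout libraries. The window of Tcra and Tcrd (T cell receptor alpha and delta) held 64 and 61 in WT and 68 and 72 in knockout libraries. Of the smaller loci, Igl held 9 and 8 against 9 and 9 peaks, Tcrb 13 and 11 against 10 and 14, and Tcrg 5 and 5 against 5 and 7. Mean densities were 37.3 peaks per Mb in Igh, 30.2 in Igk and 33.1 in Tcra and Tcrd, against 9.02 over the chromosomes. Among 10000 random windows of equal length these 3 densities lay at percentiles 99.9, 99.5 and 99.4, and those of Igl, Tcrg and Tcrb at 94.3, 79.9 and 76.1, a comparison that was not among those set in advance.

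Over the 6 loci together, WT libraries held 295 ± 7.1 peaks and knockout libraries 312 ± 11.3 (mean ± SD, n = 2 each, exact permutation p = 0.333, the lowest possible). The knockout counts were higher by 4 for replicate 1 and by 30 for replicate 2. With the same number of peaks from every list the difference in receptor-locus peaks was 3.5, and among peaks with a fold of at least 4 it was −35.5. Without the second knockout library it was 9. In the receptor loci 24 of 429 regions followed genotype (5.59%), 16 of them knockout-only and 8 WT-only, against 5.23% of regions elsewhere (odds ratio 1.07, Fisher's exact p = 0.743). In none of the 6 loci was a difference from the rest of the genome in this share detected, with Benjamini-Hochberg adjusted p of 0.742 or more in Fisher's exact test. Igl and Tcrg, with 9 regions each, and Tcrb, with 16, are too small for this test to detect a lower share. In Igh 79 of 140 regions (56.4%) were called in all 4 libraries, more than the 41.63% elsewhere (adjusted Fisher's exact p = 0.0033), and in Igl 8 of 9 were (adjusted p = 0.015). In Igk the share was 36.6% (adjusted Fisher's exact p = 0.402). The test of regions called in all libraries was not among those set in advance.

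Named sites in the loci were as follows. The strongest shared Igh region lay on chromosome 12 at 117205765 to 117206315, with folds of 6.98 and 6.81 in WT and 6.96 and 5.16 in knockout lists, which are percentiles 97.0 to 99.4 of their own lists. In Igh, 6 regions were knockout-only and 4 WT-only. By the lower of their folds, the first knockout-only one lay at 116343660 to 116343957 (folds 4.91 and 4.91), and the first WT-only ones at 116933886 to 116934314 (5.56 and 4.76) and 116435603 to 116435894 (4.11 and 4.54). The strongest shared Igk region lay on chromosome 6 at 70718295 to 70719202, with folds of 6.27, 6.79, 6.12 and 4.82. Igk held 7 knockout-only regions, among them 67904332 to 67904926, and 4 WT-only regions, among them 69458031 to 69458517. The strongest shared regions of the other loci were chromosome 16 at 19262785 to 19263841 for Igl, chromosome 14 at 53695536 to 53696265 for Tcra and Tcrd, chromosome 6 at 41212659 to 41213827 for Tcrb and chromosome 13 at 19374765 to 19375560 for Tcrg. In Tcra and Tcrd 2 regions were knockout-only, in Tcrb 1, and in Igl and Tcrg 0 regions followed genotype. Peaks of the genotype-following regions ranked for naming, up to 5 per locus, had a −log10 q of at most 5.49.

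**Figure D2:**
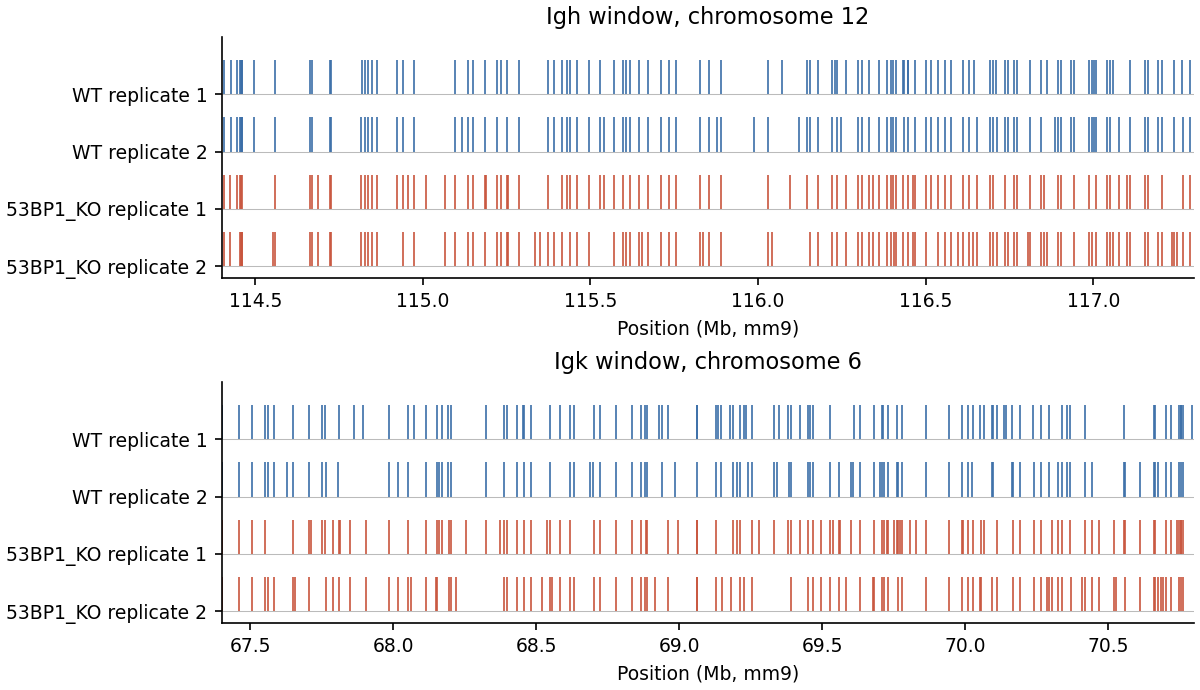
Positions of Rad21 peaks (1 vertical line per peak, of equal height) along the Igh window on chromosome 12 and the Igk window on chromosome 6, in Mb of mm9, with 1 row per library (WT blue, 53BP1 knockout red). Of the merged regions, 79 of 140 in Igh and 59 of 161 in Igk were called in all 4 libraries, and the others were missing from at least 1.

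Peaks were last compared by chromosome, to see whether whole chromosomes or segments shifted. The second knockout library held more of its peaks on chromosomes 5 and 10 than the other 3 libraries. Chromosome 5 carried 7.74% of its peaks (Wilson interval 7.40 to 8.09%), against 6.28% and 6.22% in WT and 6.18% in the first knockout library. Chromosome 10 carried 6.97% (6.65 to 7.31%), against 5.52% in each WT library and 5.39% in the first knockout library. The difference was thus found in 1 library and not in both knockout libraries. On 10 of 20 chromosomes the 2 knockout shares lay both above or both below the 2 WT shares, where chance gives 33.3%. The shares of a library depend on each other, since they add up to its whole list, so the excess over 33.3% was not tested. Chromosomes separated by the other pairings of libraries were not counted. The largest such differences were on chromosomes 9, with 5.59% and 5.64% in WT and 5.48% and 4.95% in knockout libraries, 8 (4.73% and 4.71% against 4.65% and 4.18%), 11 (7.26% and 7.30% against 7.12% and 6.83%), 6 (5.544% and 5.502% against 5.45% and 5.21%) and X (2.24% and 2.23% against 2.29% and 2.47%). The second knockout library carried most of each gap. Knockout minus WT, in percentage points, was −0.396 on chromosome 9 and −0.131 without that library, −0.305 and −0.071 on chromosome 8, −0.304 and −0.161 on 11, −0.192 and −0.074 on 6, and 0.143 and 0.049 on X. Without the first knockout library the differences were −0.662, −0.539, −0.448, −0.310 and 0.237 in the same order. Within the shared name prefixes the difference was −0.110 for replicate 1 and −0.683 for replicate 2 on chromosome 9, −0.084 and −0.526 on 8, −0.136 and −0.472 on 11, −0.095 and −0.289 on 6, and 0.043 and 0.243 on X. Each chromosome had an exact permutation p of 0.333, the lowest possible, and each kept its direction among peaks outside chromosomes 5 and 10, where 9 of 18 chromosomes were separated.

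In 1 Mb windows, both knockout counts exceeded both WT counts in 392 of 2302 windows and lay below both in 120. These 512 separated windows (22.2%) compared with 389 when libraries were split by replicate number and 480 when they were crossed. The crossed split, of the first knockout and second WT library against the other pair, was more uneven than the genotype split, with 398 windows higher and 82 lower. The windows with the widest gap were chromosome 10 at 79 to 80 Mb, with 44 and 44 peaks in WT and 52 and 51 in knockout libraries, chromosome 3 at 19 to 20 Mb (12 and 12 against 21 and 18) and chromosome 5 at 23 to 24 Mb (16 and 19 against 26 and 25). Of these, the windows on chromosomes 10 and 5 lie where the second knockout library held a larger share of its peaks. In the other direction, chromosome 9 at 34 to 35 Mb held 6 and 6 peaks in WT and 2 and 2 in knockout libraries, and chromosome 1 at 130 to 131 Mb held 21 and 20 against 17 and 14. With the same number of peaks from every list the balance turned, with 220 windows higher and 248 lower in knockout libraries, and at a −log10 q of at least 5 they were 40 and 218. With all peaks but without chromosomes 5 and 10, 320 windows were higher and 115 lower.

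**Figure D3:**
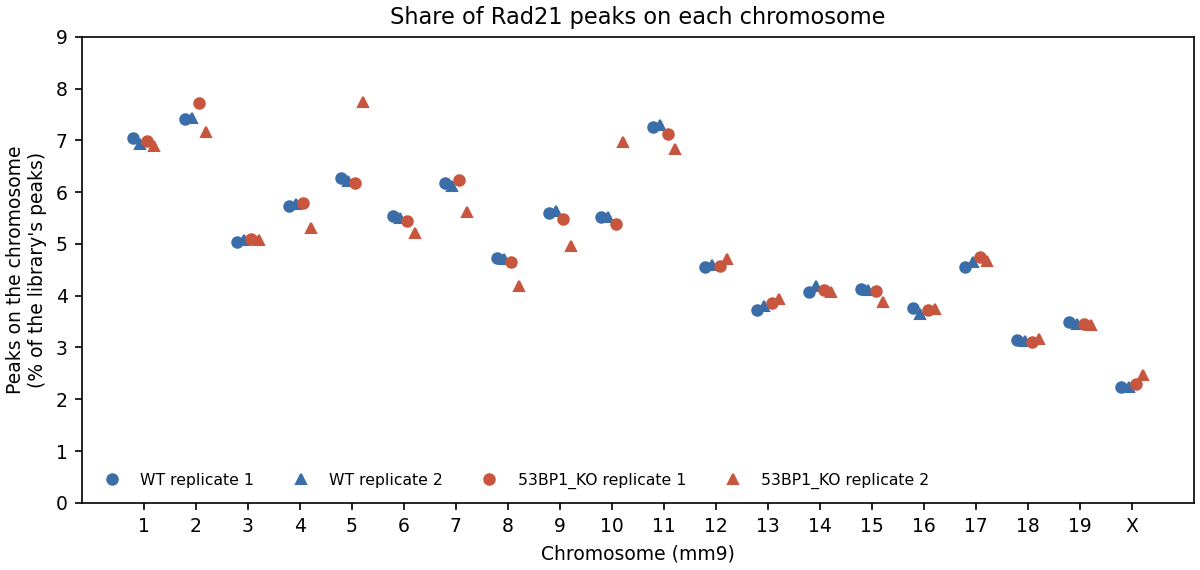
Percentage of each library's Rad21 peaks on every chromosome (circles replicate 1, triangles replicate 2, WT blue, 53BP1 knockout red). The second knockout library stands apart on chromosomes 5 and 10, at 7.74% and 6.97%, and no error bars are drawn because each point is 1 library.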

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

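Peaks on the mitochondrial sequence were outside the comparisons and are given because the lists contain them. The 4 lists held 7 such peaks in total, 1 in the first WT list and 2 in each other list. Every list had a peak near the end of that sequence, at 15128 to 16041 and 15309 to 15975 in WT and at 15296 to 16004 and 14582 to 16155 in knockout cells, with folds of 3.40, 3.21, 3.94 and 3.17. No control library was used here to set them against, so the number says nothing of their source. With 2 libraries per group, no library was tested as an outlier.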

How the results depend on the processing

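Leaving out chromosomes 5 and 10 was chosen after the result was seen; the other alternatives were not. In the replicate block, differences of peak number, covered length, width and receptor-locus peaks were taken within replicate numbers and averaged. With 1 library per genotype and number, this average equals the difference of group means. It therefore had to give the same 1468.5 peaks as the unpaired comparison. For pairwise overlap, the block instead set same-genotype pairs against between-genotype pairs of different replicate number. The Jaccard difference was then 0.010, and no value moved by more than its spread. The replicate numbers also share only a number and a peak-name prefix, so the block is no independent check. Of 68 values recomputed under the alternatives fixed in advance, leaving out a library aside, 21 moved by more than the spread between libraries or, for a count of regions or windows, by over 1.5 times. The 68 include the averaged differences of the replicate block, which could not move. At a −log10 q of at least 5, knockout minus WT became −1021 peaks, −0.68 Mb and −11.5 receptor-locus peaks, with 2348 regions in all libraries, 470 WT-only, 169 knockout-only, 12 genotype-following regions in the receptor loci, 40 higher and 218 lower windows. At a fold of at least 4 the values were −1512.5 peaks, −1.01 Mb, −35.5 receptor-locus peaks, 3989 shared and 391 knockout-only regions. These thresholds keep fewer peaks of the second knockout list (3751 and 7003) than of any other. With equal list lengths covered length differed by 0.466 Mb and receptor-locus peaks by 3.5, with 220 higher and 248 lower windows. Reciprocal overlap raised the percentile of genotype-only regions from 32.0 to 38.2, and windows of 5 Mb, being fewer, gave 135 higher and 19 lower; the cause of the first was not tested. Leaving out 1 library gave ranges of 292 to 2645 for peaks, −0.026 to 0.054 for the Jaccard difference, −2.99 to 5.53 for the difference in percent of shared peaks, 1657 to 2917 WT-only and 1946 to 4906 knockout-only regions, 57 to 86 genotype-following receptor regions, and 574 to 984 higher and 227 to 627 lower windows; with fewer libraries a region needs fewer calls to follow genotype. The lowest knockout-only and highest WT-only counts came without the first WT library, and the highest knockout-only and lowest WT-only counts without the second knockout library. The lowest peak difference, 292, came without the first knockout library. Leaving out chromosomes 5 and 10 moved none of the 10 values it was run on beyond these limits and gave 887 knockout-only and 693 WT-only regions. The alternatives for gene lists, genomic features and the CTCF motif were not run. Because read depth is unknown, a region absent from a list cannot be told from one below its threshold.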

Other observations

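All tests in this part were chosen after the result they examine had been seen. Rad21 peaks were densest on chromosomes 11 and 19, with 13.9 ± 0.87 and 13.8 ± 0.77 peaks per Mb (SD over 4 libraries), and sparsest on X, with 3.28 ± 0.24. Of 2302 windows of 1 Mb, whose median held 8.25 peaks, the densest were chromosome 10 at 80 to 81 Mb (50.5 ± 5.6 peaks) and 79 to 80 Mb (47.8 ± 4.3). The third and the fourth lay inside receptor windows: chromosome 14 at 53 to 54 Mb, in Tcra and Tcrd, with 45 ± 1.8 peaks, and the 1 Mb of chromosome 12 from 116 Mb, in Igh, with 43.8 ± 2.9. Regions called in all 4 libraries were spaced by a median of 30.9 kb in Igh and 25.2 kb in Tcra and Tcrd, against 60.9 kb over the genome and 47.3 kb in Igk.

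The second knockout library had 14.7% of its peaks on chromosomes 5 and 10. An effect of 53BP1 loss common to both knockout libraries is argued against by the first knockout library. Its share was 11.6%, below both WT libraries (11.8% and 11.7%). This share cannot decide whether loss of 53BP1 led to the excess in the second knockout library only. A few loci as the source are argued against by the 10 Mb windows of both chromosomes. Window counts were divided by each library's peaks outside chromosomes 5 and 10. Of these windows 29 of 29, or 100%, had their largest value in the second knockout library. The 25% that chance gives takes no account of these chromosomes having been picked for the excess in the second knockout library. Stronger enrichment over local background is argued against by its own list, where the median folds at shared regions were 3.72 on chromosome 5 and 3.67 on chromosome 10, not above the other autosomes (3.75 to 3.90), as in the other 3 lists, where both chromosomes also lay at or near the lowest autosome. The median −log10 p in this list were 6.70 and 7.29, above the highest other autosome (6.35), and in none of the other 3 lists were they above it. A hypothesis that these values leave open is that this culture carried extra copies of chromosomes 5 and 10. Extra copies would give more reads without a higher fold only if the background came from the same cells. Whether a control library was used, and from which cells, is not given. Read coverage, which would test the hypothesis, was not used here.

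The regions that follow genotype form the second pattern. Counting each pairing by the geometric mean of its 2 exclusive counts, so that every library enters once, gave 897 regions for genotype, 792 for replicate number and 692 for the crossed pairs, a ratio of 1.21 to the mean of the others (95% bootstrap interval 1.14 to 1.29, which covers variation among chromosomes of these 4 libraries and none between libraries). Unequal list lengths alone are argued against by a ratio of 1.195 (1.13 to 1.26) for these libraries with the same number of peaks from every list. Median percentiles of fold of at most 37.3 for genotype-only and 36.9 for mixed-pair regions leave open whether peaks near the calling threshold matter, since a region missing from 2 lists is weak in any pairing, and stricter filters differed: at a −log10 q of at least 5 the counts were 282, 236 and 246 (ratio 1.17, 1.06 to 1.29), and at a fold of at least 4 they were 564, 511 and 563 (1.05, 0.997 to 1.11). With all peaks 1 of the 3 pairings gave as many regions, the real one at 897 against 792 for the highest other, and 3 pairings are too few for a share under 0.05; a small effect of genotype and differences between clones both stay open, since the labels do not separate them.

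The strongest shared regions form the third pattern. Of the 20 regions with the highest within-list fold percentile in all lists, 9 lay within 1 Mb of the outermost region of their chromosome, against 2.18% of all shared regions and at most 5 of 20 in 10000 random draws (permutation p = 0.0001, the smallest the draws can give). The draws take regions as independent, although strong regions can lie close together, as those at 166527145 and 166649928 on chromosome X did. This p may therefore overstate how rare the excess is. This count describes the pattern and bears on no cause of it: repeats or collapsed sequence at chromosome ends and strong cohesin sites there would give the same excess and cannot be told apart by it. Neither a repeat annotation nor a control library was used here, and no biological explanation was tested.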
